A study of Mus musculus with 12 samples.

How the data were processed

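RNA from T cells and macrophages purified out of cell suspensions of mouse lung tumours was counted on a NanoString panel of 770 mouse immune genes. The 12 libraries fall into 6 groups of 2, each cell type under vehicle, JQ1 or ricolinostat. The labels do not say whether the 2 libraries of a group come from separate animals, so each p-value measures the spread between libraries, which may be technical. Replicate numbers follow the order of the records. Each label holds 2 running numbers. Between T cell and macrophage libraries of the same treatment and replicate the last number differs by 6 in all 6 pairs, and the first by 7 in 5 of the 6. The exception is ricolinostat replicate 2, whose first numbers are 33 and 34, against 8 to 21 in the other 10 libraries. The deviations of such pairs from their group means correlated at 0.135 under vehicle, 0.250 under JQ1 and 0.790 under ricolinostat across 659 genes, all above 0.1, so they were taken as pairs in an added fit. The ricolinostat value includes the departure that both replicate 2 libraries share, described below, so it is weak evidence of pairs. Libraries of different treatments have no pairs.

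The deposited table holds 1 normalised signal per gene and library on a linear scale, a unit the labels do not state and that was read from the values. The method of normalisation is not given in the sources used here. In every library the low values above the floor lay on a lattice, 100% of them within 0.1 of a step, which is what a background constant taken off each count and 1 factor per library would leave. The step gives the signal that 1 count carries, and total signal divided by it gives the counts above background, an estimate of depth. These ran from 1454800 to 2082200 in the T cell libraries and from 773600 to 1542200 in the macrophage libraries. Whole counts were not recovered, so counting intervals are not given, and genes near 20 rest on few counts. Of the 770 symbols 754 matched a GRCm38.p6 gene table, 10 matched by a synonym or by letter case, and 6 did not; the table served for names only and no coordinates were used.

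Differences were tested with limma 3.58.1 in R 4.3.3 on log2(signal + 1), with 1 mean per group, moderated variances, two-sided p-values and Benjamini-Hochberg (BH) adjustment over the genes tested, at a threshold of 0.05. JQ1 minus vehicle, ricolinostat minus vehicle and ricolinostat minus JQ1 were fitted in the 6 libraries of each cell type. Macrophages minus T cells, and the difference between a drug's effects in the 2 cell types, were fitted in all 12. A gene was tested where at least 2 libraries of the fit exceeded 20, and the 20 housekeeping genes were not tested, which left 750 to consider. These choices, the gene lists, the named genes and the alternative settings were fixed before the data were examined. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

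The 27 gene lists comprise 9 lists of cell type markers and 18 of programs. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 against the other tested genes, BH-adjusted over the lists of a comparison; an estimated correlation and fry were alternatives. The epithelial markers, with 3 measured genes, were too few to test. Lists share genes, such as 8 of the 22 measured T cell identity genes and 13 of the 25 measured macrophage identity genes.

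Named genes are, for each drug against vehicle, the 10 largest rises and 10 largest falls past the threshold with both treated libraries on the same side of both vehicle libraries. Places left were filled by the smallest unadjusted p with that separation. Separation of 2 libraries from 2 is common and is no evidence for a single gene. It held for 427 of 630 genes under JQ1 and 241 under ricolinostat in T cells, and for 291 and 157 of 564 in macrophages. Added to these were 10 T cell and 13 macrophage genes chosen in advance, 5 per direction for the other contrasts or 3 where none passed, and the 2 to 4 largest members of a list. Where every library of a group stood at or below 20, the fold is given as at least the other group's mean on the log2(signal + 1) scale over a signal of 20 on that scale, since a fitted difference then depends on the pseudocount.

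The test was checked on simulated data with the fitted variances of JQ1 minus vehicle. In T cells it recovered 2.99% of true log2 changes of 1, 38.8% of 2 and 89.4% of 4, with 1 false call among 425 unchanged genes. In macrophages it recovered 1.49%, 14.9% and 81.8%, with 1 false call among 344. Without ricolinostat replicate 2 the shares were 65.7%, 91.0% and 95.5% in T cells, with 2 false calls, and 61.2%, 91.0% and 93.9% in macrophages, with 7. Each simulated library was given the gene's fitted SD, which the ricolinostat replicates raise. In T cells the SD of the log2 difference between replicates was 2.21 under ricolinostat, 0.646 under vehicle and 0.852 under JQ1. With ricolinostat replicate 2 in the fit, simulated vehicle and JQ1 libraries thus vary more than the real ones, and the shares need not hold for those. The other comparisons were not simulated.

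Alternatives were scaling on housekeeping genes, centring on the median, quantile normalization, a pseudocount of 10, no filter, a filter at 50, an intensity trend, a 12-library fit and leaving out each library. These were fixed in advance. Fits of the vehicle and JQ1 libraries alone, fits of all libraries but both ricolinostat replicate 2, and 12-library fits with these pairs as a replicate block, were chosen after the data were seen. A count model was planned for raw counts and was not run, because the values are normalised.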

Results

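Transcripts of 770 immune genes were counted in T cells and macrophages purified from mouse lung tumours. The mice had received vehicle, JQ1, an inhibitor of the bromodomains that read acetylated histones, or ricolinostat, an inhibitor of histone deacetylases with a preference for HDAC6. Each of the 6 combinations of cell type and treatment has 2 libraries. Counts above background were 1881200 and 1876700 in the vehicle T cell libraries, 2082200 and 2013600 under JQ1, and 1930100 and 1454800 under ricolinostat. In macrophages they were 1229100 and 773600 under vehicle, 1542200 and 1499000 under JQ1, and 1056100 and 982890 under ricolinostat. Between 508 and 635 genes per library exceeded a signal of 20.

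T cell markers set the vehicle T cell libraries apart from the macrophage libraries, while macrophage markers were abundant in both. The median signal of 22 T cell identity genes, which include the CD3 chains, Lck and Zap70, was 268 and 218 in the vehicle T cell libraries and 133 and 76.3 under ricolinostat. It was 9.41 and 4.61 in the JQ1 T cell libraries, and 2.12 to 7.41 in the macrophage libraries. The median of 25 macrophage identity genes, such as Cd68 and Csf1r, lay between 2918 and 6271 in the T cell libraries and between 3416 and 5543 in the macrophage libraries. Cd68, a lysosomal protein of macrophages, averaged 38389 in vehicle T cell and 44722 in vehicle macrophage libraries. The epithelial genes Epcam, Cdh1 and Muc1 had a median of 1561 and 1621 in vehicle T cell libraries, 4926 and 4649 under JQ1 and 4890 and 2486 under ricolinostat, against 91.5 to 607 in macrophage libraries. Lyz2 and Chil3, lysozyme and a chitinase-like protein of lung macrophages, made up 27.5% to 34.9% of all signal in 10 libraries, and 12.8% and 13.2% in ricolinostat replicate 2 of T cells and of macrophages.

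**Figure D1:**
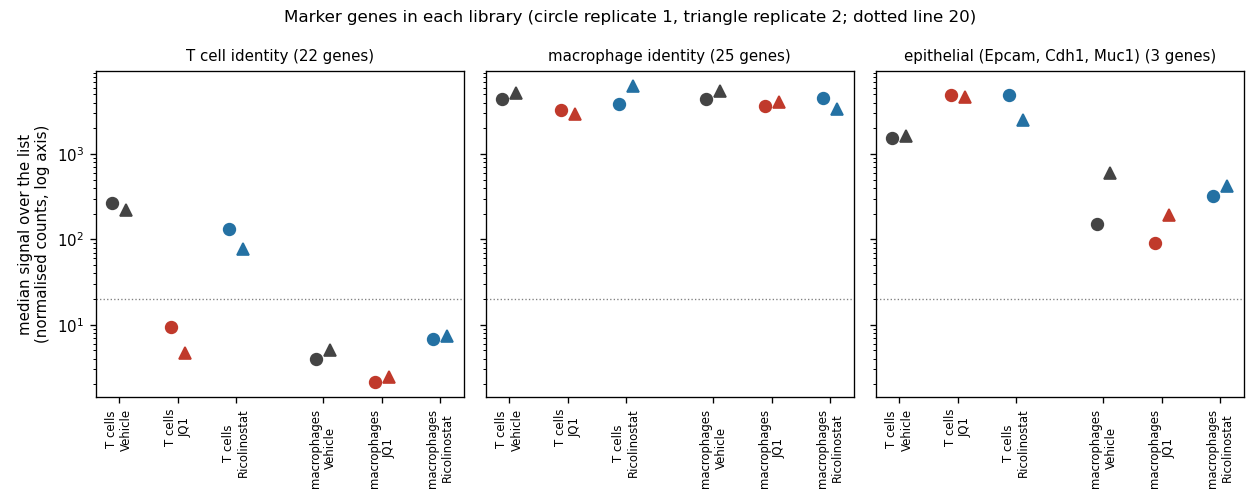
Median signal (log axis) of the T cell identity, macrophage identity and epithelial lists in each of the 12 libraries, with 1 symbol per library and a dotted line at 20. The JQ1 T cell libraries lie at 9.41 and 4.61 for T cell identity, next to the macrophage libraries, and at 4926 and 4649 for the epithelial genes.

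The ricolinostat replicate 2 libraries of both cell types stood apart from the other 10 in genes of every level, housekeeping genes included. H2-Eb1, an MHC class II chain, read 759 and 290877 in the 2 ricolinostat T cell libraries and 912 and 402722 in the 2 macrophage ones. Their Spearman correlation with each other was 0.928 across genes, and with the other libraries 0.778 to 0.861, where replicates of the other 4 groups correlated at 0.970 to 0.985. The SD of the log2 difference between ricolinostat replicates was 2.21 in T cells and 2.67 in macrophages, against 0.646 to 0.852 in the other groups. Among the 20 housekeeping genes it was 2.10 and 2.66, against 0.124 to 0.199. Counts of genes called are therefore given with and without both libraries, a choice made after the data were seen. Sizes of single genes under ricolinostat include these libraries unless stated.

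**Figure D2:**
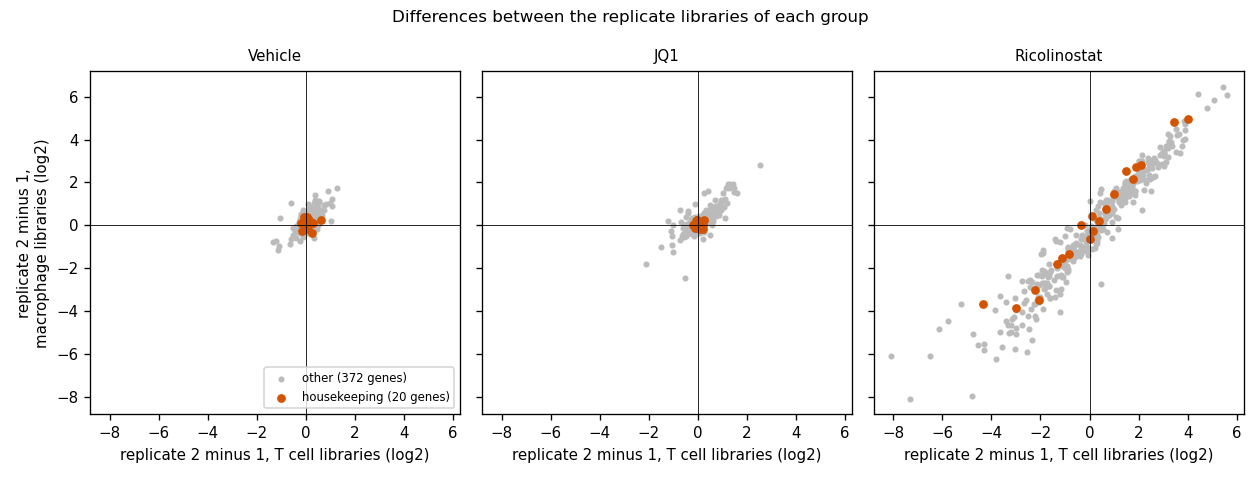
Log2 difference of replicate 2 minus replicate 1 in T cell libraries (horizontal) and macrophage libraries (vertical) for each treatment, with 1 point per gene above 100 in the other 10 libraries (372 genes, grey) or housekeeping gene (20 genes, orange). Under ricolinostat the points spread along the diagonal, with a correlation of 0.977 across the housekeeping genes.

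Macrophages against T cells. Most T cell identity genes were lower in the macrophage libraries, and most macrophage identity genes did not pass with all 12 libraries. The contrast averages vehicle, JQ1 and ricolinostat, and most T cell identity genes stood at background in the JQ1 T cell libraries. Cd3e averaged 498, 2.98 and 214 in the T cell libraries under vehicle, JQ1 and ricolinostat. Sizes and list medians of such genes are thus smaller here than under vehicle alone. Lck, the kinase that starts T cell receptor signalling, was at least 7.57-fold lower (limma, BH-adjusted p = 2.90e-05). Pdcd1, which encodes PD-1, stood at background in all 6 macrophage libraries, at least 3.21-fold lower (adjusted p = 1.55e-04). The largest differences were Dusp4, a MAP kinase phosphatase, at -7.16 ± 0.70 (SE), the lymphocyte transcription factor Ets1 at -6.85, the airway epithelial chemokine Cxcl15 at -6.26, the basement membrane collagen Col4a1 at -5.91 and the interleukin-18 receptor chain Il18r1 at -5.59, with limma adjusted p from 5.33e-05 to 0.00197. Higher in macrophage libraries were H2-Q1, a nonclassical MHC class I gene, at least 2.36-fold (96.7 ± 2.71 (SD, n = 2) against 1.68 ± 0.622 (SD, n = 2) under vehicle), Spink5 (at least 2.83-fold), the NK receptor gene Klra5 (at least 1.55-fold), the cytokine Il19 (log2 difference 2.43) and Il12b, the p40 chain of interleukin-12 and interleukin-23 (at least 1.71-fold).

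Of 22 T cell identity genes 16 were lower in macrophage libraries and none higher (18 lower when adjusted over the list alone), with a median log2 difference of -2.70, or -1.53 with genes at background held at their bound. Camera gave adjusted p = 3.41e-09 for this list, and adjusted p = 0.126 with an estimated correlation. Costimulation genes (7 of 12 lower, adjusted p = 0.0147) and naive and memory genes (5 of 7 lower, adjusted p = 0.0147) also passed camera, each with adjusted p = 0.173 with an estimated correlation. Toll-like and other pattern receptors, sensors of microbial products, were higher as a list (23 of 26 positive, adjusted p = 0.0309, and adjusted p = 0.232 with an estimated correlation), with 0 of 26 past limma on their own. Among 25 macrophage identity genes 22 did not pass and 3 were lower in the macrophage libraries, the complement genes C1qa at -3.16 and C1qb at -2.99 and the fractalkine receptor Cx3cr1 at -2.75. Csf1r (-0.26, adjusted p = 0.801), Itgam (-0.65, adjusted p = 0.731) and Cd86 (-0.27, adjusted p = 0.805) were among those not past limma, and Csf1r and Cd86 turned positive when libraries were centred on their medians. Without both ricolinostat replicate 2 libraries 11 of the 25 were higher in macrophage libraries and 3 lower, and of the pattern receptors 13 were higher and 1 lower. The stromal and endothelial list had 5 of 12 lower, among them Pecam1 (at least 5.31-fold) and Col1a1 (at least 5.81-fold), without a camera call (adjusted p = 0.0537).

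In all, limma placed 14 of 659 genes higher and 110 lower in macrophages. Without both ricolinostat replicate 2 libraries it placed 130 higher and 156 lower, 116 of them shared with the 12-library result. With T cell and macrophage libraries of the same treatment and number as a replicate block it placed 115 higher and 165 lower. The block also takes up the departure that both ricolinostat replicate 2 libraries share, so its gain need not come from pairs. Under that block Itgam (adjusted p = 0.0437), H2-Ab1 (-0.52, adjusted p = 0.0470) and Arg1 (-2.37, adjusted p = 0.00186) passed as lower and Gzmb (1.63, adjusted p = 0.00972) as higher. MHC class I and interferon response genes passed camera as higher under it (adjusted p = 0.0114 and 0.0373, against 0.0580 and 0.0887 without it), and each had adjusted p = 0.736 under it with an estimated correlation. Centring moved the median over all genes from 0.02 to 0.43 and gave 43 higher and 86 lower, and quantile normalization gave 59 and 60. The 14 became 6 to 8 without any 1 of the 4 macrophage vehicle and JQ1 libraries, either vehicle T cell library or T cell JQ1 replicate 1, and 26 without macrophage ricolinostat replicate 2. Camera called 7 lists without T cell JQ1 replicate 2, macrophage vehicle replicate 2 or macrophage JQ1 replicate 1, and the pattern receptor call ended without macrophage ricolinostat replicate 1 (adjusted p = 0.0768).

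JQ1 against vehicle in T cells. Of 22 T cell identity genes 5 and 7 stood above a signal of 20 in the 2 JQ1 libraries, against 21 and 22 under vehicle. Cd3e, a chain of the T cell receptor complex, was 498 ± 93.0 (SD, n = 2) under vehicle and 2.98 ± 2.03 (SD, n = 2) under JQ1, a fall of at least 23.5-fold (limma, BH-adjusted p = 0.0123). Il2rb, a receptor chain for interleukin-2 and interleukin-15, fell at least 30.6-fold, from 651 ± 152 (SD, n = 2) to 2.27 ± 1.02 (SD, n = 2) (limma adjusted p = 0.0123). Thy1, Cd3g, Icos and Cxcr6, a chemokine receptor of tissue-resident T cells, fell at least 28.7-, 39.1-, 39.5- and 27.8-fold, with limma adjusted p of 0.0147, 0.0386, 0.0147 and 0.0123. The inhibitory receptors Pdcd1 and Ctla4 fell at least 14.0- and 19.2-fold, both with limma adjusted p of 0.0123.

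Cd247, the CD3 zeta chain, fell at least 15.0-fold, and Cd8a, of cytotoxic T cells, at least 7.12-fold, from 153 ± 50.9 (SD, n = 2) to 1.65 ± 0.912 (SD, n = 2) (limma adjusted p = 0.0147). Il2ra, the high-affinity interleukin-2 receptor chain of regulatory and activated T cells, fell at least 15.0-fold (limma adjusted p = 0.0147), and Foxp3, the regulatory T cell factor, at least 1.80-fold from 37.2 ± 7.21 (SD, n = 2) (limma adjusted p = 0.0133). Cd4 was 237 ± 56.5 (SD, n = 2) under vehicle and 86.5 ± 1.18 (SD, n = 2) under JQ1 (limma adjusted p = 0.795, and 0.0361 without ricolinostat replicate 2). It does not part the cell types here. In macrophage libraries it was 315.5 ± 234 (SD, n = 2) under vehicle and 118 ± 18.9 (SD, n = 2) under JQ1. The effector genes Ifng, Gzmb and Prf1 were at least 2.18-, 2.66- and 2.62-fold lower and did not pass limma (adjusted p = 0.148, 0.392 and 0.261), with every JQ1 library at or below 20.

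**Figure D3:**
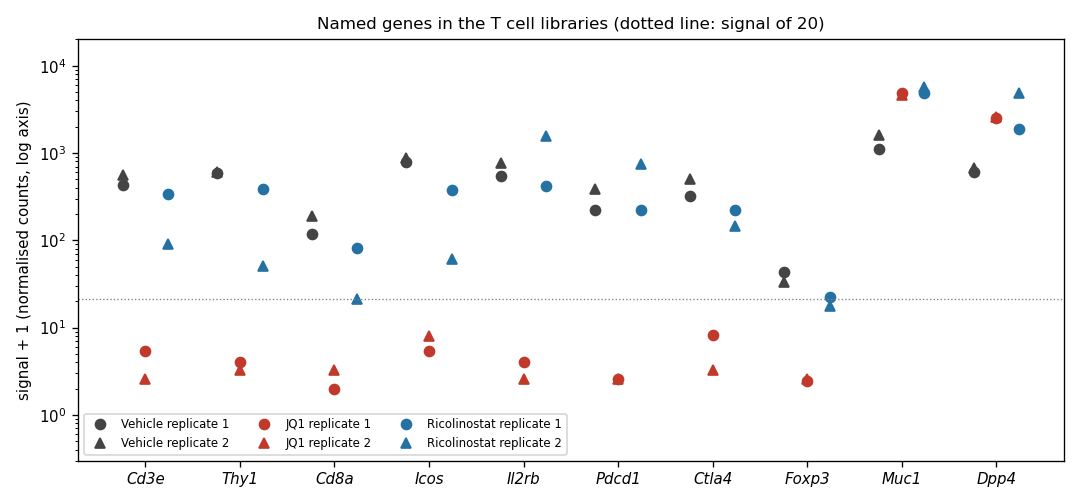
Signal plus 1 (log axis) of 10 named genes in the 6 T cell libraries, with color for treatment, symbol for replicate and a dotted line at a signal of 20. The 8 T cell genes from Cd3e to Foxp3 lie below the line in both JQ1 libraries, and Muc1 and Dpp4 lie higher under JQ1 than under vehicle.

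Of 22 T cell identity genes 13 fell, none rose and 9 did not pass (20 fell when adjusted over the list alone). The median was -4.79 on the log2 scale, or -3.15 with genes at background held at their bound, against -0.38 over all 630 genes (camera adjusted p = 1.59e-19, and adjusted p = 0.0440 with an estimated correlation, which became 0.454 without ricolinostat replicate 2). Of 16 cytotoxic genes 6 fell (13 adjusted over the list alone), Cd8b1 (at least 4.13-fold) and the NK receptor Klrd1 (at least 9.19-fold) among them. Of 12 costimulation genes 4 fell (10 over the list alone), and of 16 regulatory T cell genes 5 fell (5 over the list alone), with the chemokine receptor Ccr4 at least 2.78-fold lower. These 3 lists passed camera with adjusted p of 1.11e-09, 1.80e-06 and 1.59e-04, and each had adjusted p = 0.137 with an estimated correlation. Smaller lists passed as well: type 2 helper genes (3 of 6 fell, including the transcription factor Gata3 at least 7.55-fold; adjusted p = 0.00569), naive and memory genes (2 of 7 fell, adjusted p = 0.00880), NK cell genes (2 of 7 fell, adjusted p = 0.00880) and checkpoint receptors (2 of 10 fell, adjusted p = 0.0457). For these 4 the values were adjusted p = 0.279, 0.257, 0.279 and 0.342 with an estimated correlation, and none of them passed without either ricolinostat library (adjusted p = 0.114, 0.115, 0.188 and 0.165 without replicate 2). Checkpoint receptors also lost the call without T cell vehicle replicate 2 (adjusted p = 0.0646) or JQ1 replicate 2 (adjusted p = 0.112).

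In the same libraries Muc1, an epithelial mucin, was 4787 ± 195 (SD, n = 2) under JQ1 and 1359 ± 371 (SD, n = 2) under vehicle (limma adjusted p = 0.142, and 0.0273 without ricolinostat replicate 2). Msln, Dpp4, Cxcl5 and Il34 had log2 differences of 2.32, 2.01, 1.77 and 1.74, and Dock9, Il22ra1, Pvrl2, Igf2r and Smpd3 of 1.24 to 1.67. None of these passed with all 6 libraries, and Dpp4 (0.00932), Cxcl5 (0.0246), Il34 (0.0304), Pvrl2 (0.0431) and Igf2r (0.0246) passed without ricolinostat replicate 2 (limma adjusted p). The median of 14 stromal and endothelial genes was 50.1 and 26.3 under JQ1 against 179 and 104 under vehicle, without a camera call for the 12 tested (adjusted p = 0.696), and the member Col4a1 averaged 1311 against 408. No gene of the macrophage identity list passed, and its median log2 difference was -0.50 (camera adjusted p = 0.953), close to the -0.38 of all genes. The median of 10 dendritic cell genes was 38.6 and 36.3 under JQ1 against 163 and 200.4 under vehicle, with 2 of 8 tested genes lower, Ccr7 (-3.40) and Itgae (at least 8.30-fold), which T cells also express (camera adjusted p = 0.496).

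Altogether limma called 35 genes lower and 0 higher at adjusted p below 0.05, and 93 at an unadjusted p below 0.05. Quantile normalization left 8 lower and centring 26. Without ricolinostat replicate 2 it called 25 higher and 77 lower, all 35 among them, and without replicate 1 the counts were 25 and 77 too. Leaving out any 1 of the 4 vehicle and JQ1 libraries left 0 calls, with 50 to 55 genes at an unadjusted p below 0.05, where the lone library was taken to vary like the other groups.

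Ricolinostat against vehicle in T cells. Most T cell genes stayed above background, and 0 of 630 genes passed limma, with 18 at an unadjusted p below 0.05. Cd3e averaged 214 ± 177 (SD, n = 2), Pdcd1 481 ± 368 (SD, n = 2) and Foxp3 19.0 ± 3.13 (SD, n = 2), with log2 differences from vehicle of -1.50, 0.47 and -0.93, and of -0.54, -0.40 and -0.77 without replicate 2. The smallest unadjusted p belonged to Slamf7, a receptor of activated lymphocytes and myeloid cells, at least 3.08-fold lower (limma adjusted p = 0.657). Other genes lower in both ricolinostat libraries than in both vehicle libraries were Ccl8 and Twist1, at least 1.91- and 2.05-fold, and Csf1, Cxcr1, Icos, Cd53, Cd8a, Cd28 and Ccr7, at -2.89 to -1.16, and higher ones were H2-Q2 (3.31), Muc1 (1.98), Dpp4, Serpinb2, Dock9, Col4a1, Il7, C6, Smpd3 and Erbb2. All of these had limma adjusted p = 0.657. Of all 630 genes 241 lay above or below both vehicle libraries, so separation by itself says little about single genes. Cd4 was 0.92, Il2ra -0.26, Ctla4 -1.17, Ifng -0.75, Gzmb -1.88 and Prf1 0.30, none past limma. Without replicate 2 these 6 were -0.65, -0.72, -0.85, -0.83, -0.17 and -0.55. Of the genes lower or higher in both ricolinostat libraries, Csf1, Cxcr1, Icos and Cd53 had -1.31, -1.12, -1.14 and -0.97 without replicate 2. H2-Q2 had 2.19. The fitted differences of Cd28 (-1.24) and C6 (1.80) were larger without replicate 2, and those of the others named with them were smaller.

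As lists, MHC class I genes, which present peptides to CD8 T cells, were higher than other genes (12 of 13 positive, 0 past limma; median 1.04; camera adjusted p = 0.0125, and 0.869 with an estimated correlation). H2-Q2 read 164 and 781 in the 2 ricolinostat libraries, and without replicate 2 the list had adjusted p = 0.170. T cell identity (17 of 22 negative, median -0.67), cytotoxic, costimulation and regulatory genes were lower (camera adjusted p = 0.0196, 0.0234, 0.0282 and 0.0282). With an estimated correlation these 4 had adjusted p = 0.491, 0.869, 0.491 and 0.491. In the same libraries the epithelial median was 4890 and 2486, against 1561 and 1621 under vehicle. Of the 5 lists 0 passed without ricolinostat replicate 1, 2 without replicate 2 (T cell identity and regulatory genes, adjusted p = 0.00620 and 0.0434) and 2 without vehicle replicate 2 (cytotoxic genes lost at adjusted p = 0.217, costimulation and regulatory genes at 0.0672). Without replicate 2 cytotoxic and costimulation genes had 0.307 and 0.139. With replicate 2 as the only ricolinostat library, limma called 204 genes higher and 171 lower, and with replicate 1 alone it called 0, with 79 at an unadjusted p below 0.05.

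Ricolinostat against JQ1 in T cells. Il2rb, Pdcd1, the interleukin-33 receptor Il1rl1, Cxcr6 and Cd3e were at least 38.7-, 19.3-, 7.91-, 11.3- and 8.32-fold higher (limma adjusted p from 0.0225 to 0.0276). These bounds include ricolinostat replicate 2. Pdcd1 differed from vehicle by -0.40 without replicate 2 and by 1.34 without replicate 1, so its bound is smaller without replicate 2. Cd3e read 339 and 88.9 in the 2 ricolinostat libraries, so its bound is larger without replicate 2. Slamf7 was the gene called lower, at least 3.82-fold (limma adjusted p = 0.0312, and 0.0611 without replicate 2). Twist1 (at least 2.17-fold lower) and Csf1, Cxcl5 and Ly9 (log2 differences of -2.89 to -1.74) did not pass. Csf1 and Ly9 had ricolinostat replicate 2 minus replicate 1 of -3.16 and -1.19 on the log2 scale, so their differences are smaller without replicate 2. Of 22 T cell identity genes 7 rose (18 over the list alone), of 16 cytotoxic genes 2 (7 over the list alone) and of 12 costimulation genes 1 (7 over the list alone), with camera adjusted p of 1.03e-12, 1.51e-05 and 0.00782. With an estimated correlation the values were adjusted p = 0.0860, 0.394 and 0.394. The median over all 630 genes was 0.46, and the T cell identity median was 3.90, or 2.44 with genes at background held at their bound. Limma called 18 genes higher and 1 lower, 0 without any 1 of the vehicle and JQ1 libraries, 406 without ricolinostat replicate 1 and 26 higher without replicate 2. Camera called 1 list without ricolinostat replicate 1 and 6 without ricolinostat replicate 2 or JQ1 replicate 1.

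JQ1 against vehicle in macrophages. MHC class II genes, which present antigen to CD4 T cells, were lower than other genes as a list, with all 11 measured members negative and 0 past limma. H2-Aa read 16749.7 and 63514 in the 2 JQ1 libraries and 76536 and 134091 under vehicle, a log2 difference of -1.64 ± 1.03 (SE) (limma adjusted p = 0.999). H2-Ab1, H2-Eb1, the invariant chain Cd74 and the transactivator Ciita were -1.50, -1.80, -1.46 and -0.82, each with limma adjusted p = 0.999. The list had a median of -1.29 against -0.20 over all 564 genes (camera adjusted p = 0.0202, and 0.590 with an estimated correlation). The call ended without vehicle replicate 2 (adjusted p = 0.0929), JQ1 replicate 1 (0.475), ricolinostat replicate 1 (0.128) or ricolinostat replicate 2 (0.138). In T cell libraries the same 11 genes were negative under JQ1 as well (median -1.42, camera adjusted p = 0.106), and the difference between the 2 effects had adjusted p = 0.868.

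**Figure D4:**
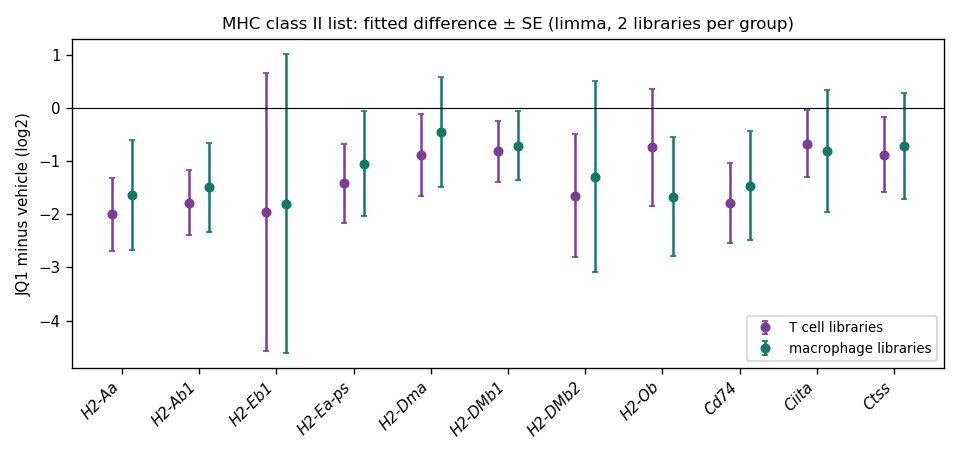
Log2 difference of JQ1 minus vehicle (points, with bars of 1 SE from limma) for the 11 measured MHC class II genes in T cell and macrophage libraries, 2 libraries per group. All points lie below 0, and 0 of 11 passed limma in either cell type.

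Dendritic cell genes were lower as a list (7 of 8 negative, led by the chemokine Ccl17 at -2.82; camera adjusted p = 0.0202), and so were 6 T cell identity genes, Zap70 (at least 3.03-fold) and Icos (at least 1.35-fold) among them (adjusted p = 0.0202). Both had adjusted p = 0.590 with an estimated correlation. The dendritic call ended without vehicle replicate 2 (0.0822), JQ1 replicate 1 (0.0868) or either ricolinostat library (0.128 and 0.138), and the T cell call without vehicle replicate 2 (0.284) or JQ1 replicate 2 (0.189). In the same libraries the epithelial median was 91.5 and 191 under JQ1 and 153 and 607 under vehicle. The complement genes C1qa (137 ± 31.9 (SD, n = 2) against 629 ± 346 (SD, n = 2)) and C1qb (-1.74), the TLR4-like receptor Cd180 (-1.42), Ncam1 and Klra15 (at least 2.21- and 1.62-fold) lay below both vehicle libraries in both JQ1 libraries. Above both lay the matrix protease Mmp9 (at least 2.57-fold), Nefl, Cxcl11, Hras, Igf2r, Flt3l, Nos2, Il6st and Socs1, and also Tigit, which was at or below 20 in both groups. Of all 564 genes 291 separated in this way, so separation by itself says little about single genes. Csf1r and Itgam each had a log2 difference of -0.02, turning positive under each scaling tried, and Cd86, Cd80, Cd40, Cd274, Arg1 and Il1b had -0.54, -0.55, -0.61, 0.18, -0.91 and -0.20. Limma called 0 of 564 genes, with 7 at an unadjusted p below 0.05, and without ricolinostat replicate 2 it called 0 with 82. Camera called 1 list without vehicle replicate 2 and 5 without JQ1 replicate 1.

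Ricolinostat in macrophages. No gene passed limma against vehicle, with 16 at an unadjusted p below 0.05, nor against JQ1, with 35, and camera called 0 of 22 lists in both. The inhibitory receptor Lag3 read 36.7 and 453 in the ricolinostat libraries and 3.96 ± 1.51 (SD, n = 2) under vehicle (at least 6.23-fold; limma adjusted p = 0.570). Tigit, Cfi, Cd27, Tnfrsf18, Erbb2, Camp, Flt3l and Dpp4 were also above both vehicle libraries, and Ncam1, Klra15 and the guanylate-binding protein Gbp2b (at least 2.21-, 1.62- and 2.18-fold) and Zap70, Cxcr1, Ly9, Timd4, Mfge8, Ifit1 and Angpt2 (-3.07 to -1.34) below both. These sizes include replicate 2. Of all 564 genes 157 lay above or below both vehicle libraries, so separation by itself says little about single genes. Replicate 2 minus replicate 1 was -3.59 for Cxcr1 and -1.73 for Ly9 on the log2 scale, so their falls are smaller without replicate 2, and -0.178 for Mfge8. Itgam (0.94), Cd86 (0.15), Cd80 (0.57), Cd40 (0.29) and Cd274 (0.53) were positive with both libraries and negative without replicate 2. Csf1r, Il1b, Cd74, H2-Ab1 and H2-Eb1 were 0.91, 1.78, 1.21, 0.27 and 4.94, and H2-Aa, Ciita and Arg1 -0.84, -0.65 and -2.39, with limma adjusted p from 0.570 to 0.856. Without replicate 2 these were 0.27, 0.34, 0.25, 0.18 and 0.55, and 0.17, 0.69 and -0.32. Against JQ1, Pdcd1lg2 and Muc1 had log2 differences of 3.73 and 2.60, and Cfi and Tnfrsf18 were at least 1.52- and 3.15-fold higher. Csf1, Slamf7 and Ly9 had -3.11 to -2.37, and Gbp2b and Mmp9 were at least 1.33- and 2.57-fold lower. Each had limma adjusted p = 0.584, and the median over all genes was 0.34. Those sizes include replicate 2 as well. Replicate 2 minus replicate 1 was -4.38 for Csf1, so its difference is smaller without replicate 2. Cfi read 40.2 and 23.6 in the 2 ricolinostat libraries, so its bound is larger without replicate 2. With replicate 2 as the only ricolinostat library limma called 361 genes against vehicle and 348 against JQ1, and without it 0, with 20 and 47 at an unadjusted p below 0.05. Against JQ1 camera called 1 list without JQ1 replicate 1.

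Differences between the drug effects in the 2 cell types. The difference tested is the JQ1 or ricolinostat effect in macrophages minus that in T cells. Limma called 6 of 659 genes, all higher: Il2rb, Pdcd1 and Cd3e (adjusted p = 0.0255 each), Cxcr6 (0.0330), the T cell receptor regulator Cd6 (0.0384), and Thy1 (0.0425, outside the naming rule and added after its value was seen). All 6 stood at or below 20 in the JQ1 T cell libraries and in the macrophage libraries, so none could fall in macrophages and no size is given. With the replicate block it called 3, Il2rb (adjusted p = 0.0227), Cd8b1 (0.0325) and Xcl1 (0.0442), the last 2 outside the rule and added after their values were seen, and the other 5 had 0.0571 to 0.0622. T cell identity (3 of 22 called, 14 over the list alone), cytotoxic, costimulation, regulatory, naive and memory, and type 2 helper genes passed camera in the same direction, which for members at background in macrophage libraries restates the effect in T cells (adjusted p = 1.41e-21, 2.98e-07, 1.60e-05, 1.70e-04, 6.08e-04 and 0.0186). T cell identity, costimulation and regulatory genes kept the call with adjusted p = 0.0126, 0.0325 and 0.0343 with an estimated correlation, and without both replicate 2 libraries these 3 became 0.377, 0.478 and 0.478. The other 3 had adjusted p = 0.0540, 0.0540 and 0.170 with it. With the replicate block the type 2 helper list had 0.0655 and the complement list passed as lower (0.0371, against 0.0545 without it). With an estimated correlation under the block, T cell identity, costimulation and regulatory genes each had 0.241 and complement genes 0.514. The type 2 helper call also ended without T cell JQ1 replicate 2 (0.0621) or macrophage vehicle replicate 1 (0.0503). For ricolinostat limma called 0 of 659 genes, with 12 at an unadjusted p below 0.05, and the smallest p belonged to Cd27 (adjusted p = 0.468), Tigit and Cd28. T cell identity, costimulation, regulatory, and naive and memory genes passed camera (adjusted p = 3.56e-07, 5.04e-06, 9.07e-04 and 9.07e-04), with adjusted p = 0.0569, 0.0473, 0.0569 and 0.0569 with an estimated correlation, and 0 lists passed without both replicate 2 libraries. Here too, members at background in macrophage libraries could not fall there. The signal of 1 count, at which Cd6 stood, was 2.90 and 5.03 in vehicle and 3.51 and 7.41 in ricolinostat macrophage libraries. Genes at that floor thus add a positive difference without a change in counts. With the replicate block regulatory and naive and memory genes each had 0.0611, and costimulation genes had 0.849 with an estimated correlation. The 6 JQ1 genes became 0 without any 1 of the 8 vehicle and JQ1 libraries, 10 without either T cell ricolinostat library, 14 without either macrophage one and 36 without both replicate 2 libraries. The ricolinostat count became 1 without T cell ricolinostat replicate 1 and 5 without macrophage ricolinostat replicate 1, and its lists 1 without T cell replicate 2 and 7 without macrophage vehicle replicate 2. The regulatory list also lost its call without macrophage ricolinostat replicate 1 (adjusted p = 0.346), and the naive and memory list without macrophage ricolinostat replicate 2 (0.586). Of the 36 genes called for JQ1 without both replicate 2 libraries, 27 were higher and 9 lower. The median over all genes was 0.15 for JQ1 and 0.12 for ricolinostat.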

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

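The tests of the difference between drug effects, with the alternative pseudocount and the estimated correlation, were fixed before the data were examined. Apart from these, the correlation of ricolinostat replicates and the regrouping of libraries, the tests in this part were chosen after the results were seen. The results listed here passed a test of the difference between a drug's effects in T cells and in macrophages, and most did not pass every form of it.

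Under JQ1 the fitted effect in macrophages minus that in T cells, whose size is not measured for genes at background, was 7.08 for Il2rb, 6.38 for Pdcd1, 7.08 for Cd3e, 5.93 for Cxcr6 and 5.03 for Cd6 on the log2 scale, and limma called 6 genes in all. As lists, the median of this difference was 4.54 for T cell identity, 3.28 for cytotoxic, 2.05 for costimulation, 1.59 for regulatory, 2.45 for naive and memory and 1.72 for type 2 helper genes. Under ricolinostat the median difference was 1.33 for T cell identity, 1.28 for costimulation, 1.09 for regulatory, and 1.53 for naive and memory genes. List members at background in macrophage libraries could not fall there under either drug. Under ricolinostat the floor of the macrophage libraries was also higher than under vehicle, which adds to these 4 medians. Of these 4 lists only costimulation passed with an estimated correlation (the others had camera adjusted p = 0.0569), regulatory and naive and memory genes had 0.0611 with the replicate block, and 0 lists passed without both ricolinostat replicate 2 libraries. The 5 genes named stood at or below 20 in the JQ1 T cell libraries and in every macrophage library, so they could not fall in macrophages, and the sizes depend on the pseudocount: with a pseudocount of 10 these genes had 5.55, 4.56, 5.27, 5.09 and 3.73. The list medians depend on it too, and were 3.40, 1.98, 1.62, 1.32, 2.32 and 1.19 under JQ1 and 1.10, 1.06, 0.72 and 0.93 under ricolinostat with a pseudocount of 10.

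With the replicate block Il2rb kept the call under JQ1, while Pdcd1, Cd3e, Cxcr6 and Cd6 had limma adjusted p = 0.0622, 0.0571, 0.0578 and 0.0578, and type 2 helper genes had camera adjusted p = 0.0655. With an estimated correlation cytotoxic, naive and memory and type 2 helper genes lost the JQ1 call (adjusted p = 0.0540, 0.0540 and 0.170), and without both ricolinostat replicate 2 libraries no list passed in that form.

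Low T cell genes in both JQ1 T cell libraries. Of 11 T cell identity genes at background in macrophage libraries 0 changed by less than 1 on the log2 scale, so none of these 11 was spared. The list had been seen to be low in these libraries when this test was chosen, so the result restates the pattern. It is not separate evidence against repression of only some T cell genes in T cells that stayed as numerous. A macrophage library under a JQ1 T cell label is argued against. Genes outside the T cell lists that part the vehicle libraries stayed at a median of 4.47 between JQ1 T cell and JQ1 macrophage libraries. Of these, 38 of 46 stayed above 1. Among them are the epithelial mucin Muc1 (6.48), Cxcl15 (7.44) and the collagen Col4a1 (6.66). Il2rb, Cxcr6 and Stat4 went from 7.05, 6.60 and 4.03 under vehicle to -0.0322, 0.677 and 0.522 under JQ1. The genes that stayed therefore do not show that these libraries hold T cells. That 11 of these 11 T cell identity genes fell by more than 1 describes the pattern and does not decide for fewer T cells in these libraries. Whether the drug removed T cells from the tumour, repressed all these genes alike or the purification yielded fewer T cells stays open.

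Departure of both ricolinostat replicate 2 libraries. Low depth is argued against, since among 186 genes above 1000 the SD of the log2 difference between the macrophage ricolinostat replicates was 2.69 against 0.305 for the macrophage vehicle pair, which holds the library of lowest depth. The test for a ricolinostat response shared by both replicates does not decide. The departure is a difference between the replicates, so an equal response in both could not produce it, whatever the values. In T cells the log2 differences from vehicle of replicates 1 and 2 correlated at -0.0259, against 0.793 for JQ1, across genes, which are not independent. Under ricolinostat those of replicate 1 had an SD of 0.744, against 0.646 for the difference between vehicle replicates. With so little change in replicate 1, a low correlation does not exclude a shared response. In macrophages this correlation was 0.0574 for ricolinostat and 0.299 for JQ1, so it decides little there either. A probe or assay difference shared by the pair may be the source. The differences between replicates 2 and 1 correlated between the cell types at 0.877 across tested genes and 0.977 across housekeeping genes. Such a correlation does not point to the assay alone: across the 372 genes above 100 it was 0.640 under vehicle and 0.795 under JQ1. The first running number in the labels is 33 and 34 for these libraries and 8 to 21 for the other 10, and a change in an animal that gave both, or handling apart from the rest, was not tested and stays open.

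Macrophage genes in the T cell libraries. Exchanged labels are argued against, since the highest T cell identity median among macrophage libraries was 7.41 and the lowest among vehicle and ricolinostat T cell libraries was 76.3. Macrophage RNA in the T cell libraries may account for the pattern. The list had been seen to be abundant in both kinds of library when its test was chosen, so the result restates the pattern. Of 25 macrophage identity genes 21 lay within 1 on the log2 scale between vehicle T cell and vehicle macrophage libraries, with a median difference of -0.23. Cd68 averaged 38389 and 44722, and 13 of the 25 genes also stand in another list. The exceptions were Cx3cr1, C1qa, C1qb and Marco, so the macrophages in question need not be those of the macrophage libraries. The cells were purified before RNA extraction, by a method the labels do not give.

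With treatment and cell type fitted as separate terms, 130 genes were higher or lower in macrophages than in T cells. Each of 99 other groupings of the 12 libraries, drawn at random, gave at most 57 genes. Those groupings mix the cell types and break up same-numbered pairs, so this bears on the count and excludes chance for no single gene. Cell type also goes with the last running number of the labels, and these cannot be told apart here.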

How the results depend on the processing

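The fits of the vehicle and JQ1 libraries alone, those leaving out both ricolinostat replicate 2 libraries and those with the replicate block were chosen after the data were seen. In the simulation of JQ1 minus vehicle with ricolinostat replicate 2 in the fit, most log2 changes of 1 and of 2 were missed; the other comparisons were not simulated. A signal of 20 stands for 2.70 to 14.0 counts above background, depending on the library. Where a group is left with 1 library, that library is assumed to vary like the other groups. Of 182 named differences 178 kept direction and call under housekeeping scaling, 170 under centring, 159 under quantile normalization, 177 under a pseudocount of 10, 182 with no filter and 179 with an intensity trend. The cause was not tested for any change below, apart from the fits with fewer libraries or fewer genes, where the loss or gain comes with them.

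With an estimated correlation, lists passed camera as 1 (JQ1 in T cells), 0 (ricolinostat in T cells), 0 (ricolinostat against JQ1 in T cells), 0 (JQ1 in macrophages), 0 (macrophages against T cells), 3 (difference of JQ1 effects) and 1 (difference of ricolinostat effects). Fry gave 0 lists for ricolinostat in T cells, 7 for ricolinostat against JQ1 in T cells, 0 for JQ1 in macrophages, 13 for macrophages against T cells and 0 for the difference of ricolinostat effects. Quantile normalization gave 8 genes for JQ1 in T cells, 6 for ricolinostat against JQ1 there and 0 for the difference of JQ1 effects, and 0 lists for ricolinostat in T cells, 1 for JQ1 in macrophages and 1 for macrophages against T cells. A pseudocount of 10 gave 7 genes for ricolinostat against JQ1 in T cells and 10 for the difference of JQ1 effects. The filter at 50 gave 11 genes and the intensity trend 3 genes for that difference, and the filter at 50 gave 2 lists for ricolinostat in T cells and 7 for macrophages against T cells. With no filter 0 lists passed for JQ1 in macrophages and 1 for ricolinostat against JQ1 in macrophages. Genes lower under JQ1 in both kinds of library numbered 118, and 103, 42 and 53 under housekeeping scaling, centring and quantile normalization, 3 scalings applied to this count after the data were seen. Vehicle and JQ1 libraries alone gave 110 genes and 4 lists for JQ1 in T cells. The replicate block, which pairs T cell and macrophage libraries, gave 280 genes for macrophages against T cells, 3 genes for the difference of JQ1 effects and 2 lists for that of ricolinostat effects. It changed no call of a named gene or list other than those given with it among the results; it moved no estimate, since the groups are balanced. Leaving out both ricolinostat replicate 2 libraries gave 286 genes for macrophages against T cells, 36 genes for the difference of JQ1 effects and 0 lists for that of ricolinostat effects.

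For JQ1 in macrophages, housekeeping scaling turned Csf1r to 0.0267 and Itgam to 0.0265, centring Csf1r to 0.28, Itgam to 0.28 and Il1b to 0.10, and quantile normalization Csf1r to 0.12 and Itgam to 0.39. For ricolinostat in macrophages quantile normalization turned H2-Ab1 to -0.37 and Cd274 to -0.29. Between macrophages and T cells, housekeeping scaling turned Cd80 to -0.0435; centring turned Csf1r to 0.15, Cd86 to 0.14, H2-Aa to 0.0476, H2-Eb1 to 0.17, Cd74 to 0.0443, Ciita to 0.00280 and Il1b to 0.16; quantile normalization turned Itgam to 0.0869 and Ciita to 0.38. None of these passed limma.

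Leaving out 1 library at a time gave, from lowest to highest, 0 to 102 genes and 4 to 9 lists for JQ1 in T cells, 0 to 375 genes and 0 to 5 lists for ricolinostat in T cells, and 0 to 406 genes and 1 to 6 lists for ricolinostat against JQ1 there. In macrophages it gave 1 to 5 lists for JQ1, 0 to 361 genes for ricolinostat, and 0 to 348 genes and 0 to 1 list for ricolinostat against JQ1. It gave 4 to 7 lists for macrophages against T cells, 0 to 14 genes for the difference of JQ1 effects, and 0 to 5 genes and 1 to 7 lists for that of ricolinostat effects.

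The lowest and highest log2 differences with 1 library left out differed in sign for these genes. For ricolinostat in T cells they were -0.65 and 2.49 for Cd4, -0.72 and 0.20 for Il2ra, -0.40 and 1.34 for Pdcd1 and -0.55 and 1.15 for Prf1, and Cd4 passed limma with replicate 2 as the only ricolinostat library (adjusted p = 0.00576). For JQ1 in macrophages they were -0.17 and 0.13 for Csf1r, -0.37 and 0.34 for Itgam, -1.81 and 0.18 for Ciita, -1.90 and 0.0856 for Arg1 and -0.63 and 0.23 for Il1b. For ricolinostat in macrophages they were -0.78 and 2.67 for Itgam, -0.21 and 0.51 for Cd86, -0.26 and 1.41 for Cd80, -0.46 and 1.03 for Cd40, -1.86 and 0.17 for H2-Aa, -0.11 and 0.65 for H2-Ab1, -1.98 and 0.69 for Ciita and -0.26 and 1.32 for Cd274. Of these Itgam, Cd80 and Cd274 passed limma with replicate 2 as the only ricolinostat library (adjusted p = 0.00844, 0.0298 and 0.0116). Between macrophages and T cells they were -0.38 and 0.66 for Cd4, -0.63 and 0.0858 for Cd86, -0.28 and 0.46 for Cd80, -1.71 and 1.22 for H2-Eb1, -0.85 and 0.0378 for Ciita, -0.0564 and 0.56 for Cd274 and -0.75 and 0.25 for Il1b.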

Other observations

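The tests in this part other than the covariance of JQ1 effects were chosen after the results were seen, and correlations between the cell types had been seen before that covariance was computed.

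A set of genes stood lower under JQ1 in both kinds of library, by a rule set after the values were seen: above 100 in the 10 libraries other than ricolinostat replicate 2, with both JQ1 libraries on the same side of both vehicle libraries. C3ar1, the receptor for the complement fragment C3a, had log2 differences of -1.96 in T cell and -2.31 in macrophage libraries. Il7r, the interleukin-7 receptor chain, had -2.66 and -1.28, the scavenger receptor Colec12 -1.86 and -1.49, and Cd180, a TLR4-like receptor, -1.17 and -1.42. The MHC class II genes H2-Aa (-2.004 and -1.64), H2-Ab1 (-1.78 and -1.50), Cd74 (-1.78 and -1.46) and H2-DMb2 (-1.65 and -1.29) belong to the set. The airway chemokine Cxcl15 was higher in both, by 2.45 and 1.14, the neutrophil chemokine Cxcl1 by 0.99 and 0.87, and the transferrin receptor Tfrc by 1.36 and 0.60. None of these passed limma in either cell type with all libraries. Of 372 genes 152 separated JQ1 from vehicle in both cell types, 118 lower in both, 12 higher in both and 22 in opposite directions. This balance rests on the scaling: after centring 42 were lower and 53 higher in both, and after quantile normalization 53 and 48, while the 11 genes named separated in the same direction under each scaling. With libraries in random order and the cell types independent, 5.56% of genes would separate in the same direction in both. Differences between replicates that both kinds of library share raise the counts above by themselves.

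A JQ1 effect read in both kinds of library is a candidate explanation: across genes, which are not independent replicates, the JQ1 effects of the 2 cell types correlated at 0.536. Their covariance was 0.138, against 0.0598 that the differences between replicates give to such means, a ratio of 2.31 that lies just above the bound of 2 set for it. Macrophage RNA in the T cell libraries would carry an effect in macrophages into both, so the 2 kinds of library need not be separate evidence.

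Replicates of the same number may share an animal: the differences between replicates 2 and 1 correlated between the cell types at 0.640 under vehicle and 0.795 under JQ1, across the 372 genes above 100. Replicate numbers follow the order of the records, and a shared day of processing would leave the same trace, so the explanations cannot be told apart.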
